A study of Cynodon dactylon with 6 samples.

How the data were processed

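Gene expression was measured by RNA sequencing of leaves. Per the labels' protocols, total RNA was isolated with a Qiagen column kit, its integrity was checked on a Bioanalyzer, and libraries followed standard Illumina methods; strandedness and read length are not given in the sources used here. The 6 libraries fall into control (0 h), heat at 42 °C for 2 h and heat for 12 h, with 2 replicates each; the titles give the group and replicate, the other labels the 0 h of the controls, and the series' design text the temperature. The study has no unheated samples at 2 h or 12 h among those analysed here, so duration of heat and time of sampling change together.

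The deposited values come as 2 tables of 111743 unigenes. The authors deposited estimated counts, reads assigned to each unigene without normalization between libraries: 99.3% of the values above 0 are whole and 300 to 440 per library carry decimals. The authors also deposited FPKM values, reads scaled to unigene length and library total. Per the submitters' processing notes the tools were Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0, with no role given; HTSeq writes whole numbers, and the counter, assembler and genome build behind the deposited counts are not given in the sources used here. The unigene IDs have the form of component and gene numbers of an assembly without a reference, 96558 components in all, of which 10681 hold more than 1 unigene. The sheet with the counts carries the name of another grass, tall fescue, but its column names are those of the bermudagrass samples. Both tables hold the same unigenes, and all 670458 cells are either 0 in both or above 0 in both. Where a value rested on at least 100 reads, 95.3% of the lengths implied by count, FPKM and library total lay within 10% of the unigene's median. All columns matched a sample by its label, and every row named a unigene.

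Estimated counts were rounded to whole numbers. Unigenes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 25828. Libraries were scaled by trimmed mean of M-values (TMM). A quasi-likelihood model (edgeR 4.0.16 in R 4.3.3, glmQLFit with robust estimation) was fitted to all 6 libraries with a mean per group, leaving 3 residual degrees of freedom, and glmQLFTest compared the groups, with Benjamini-Hochberg adjustment over the unigenes tested and a threshold of 0.05. The common dispersion corresponded to a coefficient of variation of 0.135 between replicates. The spread of each unigene was also drawn towards that of other unigenes, with a median of 9.10 prior degrees of freedom against 3 residual ones. Standard errors are the fold change divided by the square root of F. Fold limits of 2 and 8 were applied to the estimate. A fitted fold change against a group at 0 reads depends on the prior count, so folds of such unigenes are given as bounds against a floor of 3 reads over the group, and with 1 to 3 reads as a ratio with an exact 95% binomial interval; intervals and floors cover counting error only. Shares of reads are percentages of the library total, without TMM scaling. Thinned numbers are the expected number of unigenes with a read when a library is sampled down to the smallest total.

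The groups, tests, alternatives and naming rule were fixed before the data were examined. The rule took, among unigenes past the threshold with a mean of at least 10 CPM in a group and no overlap between the libraries compared, the largest rises and falls in log2 fold change; because no source used here pairs IDs with names, it stops at 2 rises and 2 falls per comparison. The 46 gene lists planned beforehand (heat shock proteins, photosynthesis, hormones and others) match on names or descriptions, so none could be tested. The planned test was for counts, and the estimated counts were tested the same way after rounding. Unigenes of one component, and near-identical gene copies, may share reads, so single unigenes are uncertain in that respect.

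The procedure was tested on simulated data drawn from the real means, dispersions and library sizes of 25828 unigenes. With 100 unigenes changed 2-fold and 100 changed 4-fold, edgeR recovered 41 and 76 for heat 2 h against control, 40 and 78 for heat 12 h against control, and 43 and 76 for heat 12 h against heat 2 h, with 21.5%, 15.1% and 19.6% of calls false. Another simulation gave the unigenes called against control in the real data their fitted fold changes and left all others unchanged. This made 7354, 13203 and 15178 changed unigenes in these comparisons, the last of them more than the 11810 called in the real data. Of these edgeR recovered 79.6%, 86.7% and 74.5%, with 3.81%, 2.60% and 2.63% of calls false. Their effects had been selected by passing the same test, so these percentages overstate the recovery of real changes in general. With few unigenes changed, 15.1% to 21.5% of calls were false, so calls near the threshold are then less certain than the adjusted p states.

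The other settings tried were other scalings (DESeq2 size factors, upper quartile), no filter or at least 5 CPM in 2 libraries, DESeq2 1.42.0, fits of the 2 groups alone, the replicate number as a block, leaving out each library, and limma 3.58.1 on log2(FPKM + 1) or log2(FPKM + 0.1), with unigenes at 1 FPKM or more in 2 libraries or without a filter. Scaling to library totals, counts summed per component and removal of the 100 most abundant unigenes were added after seeing the data, as were the time courses and abundance classes under other settings, the other rankings by abundance and the read shares without the most abundant member of a set.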

Results

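Leaf transcriptomes of bermudagrass (Cynodon dactylon), a warm-season turf and forage grass, were compared between unheated seedlings and seedlings held at 42 °C. The seedlings were 10 days old, and leaves were taken from controls labelled 0 h and from plants heated for 2 h or for 12 h. RNA sequencing gave 6 libraries, 2 per group, and the labels do not say whether the replicates came from separate plants or pools, so the p-values measure the spread between these libraries. That spread was pooled over all groups and drawn partly from other unigenes. Reads had been assigned to 111743 unigenes, gene-level units whose IDs have the form given by an assembly without a reference genome. The files do not pair unigene IDs with gene names, and no sequence or genome position of a unigene was used here. Gene families such as heat shock proteins could therefore not be followed, and the changes are described by unigene, abundance and time course.

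The libraries held 9086743 and 6313500 assigned reads for the controls, 7209018 and 7364816 for heat 2 h, and 8257635 and 9326725 for heat 12 h. At these depths 3 reads correspond to between 0.243 and 0.563 CPM (read counts scaled to library size), which is the level below which a unigene at 0 reads could still be present. Of all unigenes, 88871 had a read in at least 1 library, and 25828 passed the abundance filter and were tested. These tested unigenes held 98.6% to 99.3% of the reads of each library.

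The leaf transcriptome was dominated by a small set of unigenes before heat and was spread over many more after 12 h. The 100 most abundant unigenes of a library held 32.6% ± 0.0415 (SD, n = 2) of its reads in the controls, 28.8% ± 2.03 (SD, n = 2) after 2 h and 16.3% ± 1.23 (SD, n = 2) after 12 h. In the controls 50% of the reads fell on 514 ± 7.07 unigenes (SD, n = 2), after 2 h on 622 ± 94.8 and after 12 h on 1615 ± 73.5. Of the 100 most abundant unigenes of the controls, 68 were also among the 100 most abundant after 2 h and 40 after 12 h. Unigenes with at least 1 read numbered 49121 ± 4451 in the controls, 51039 ± 2501 after 2 h and 62268 ± 1647 after 12 h. With every library thinned to the smallest total, the numbers were 47052 ± 1526, 49340 ± 2230 and 57978 ± 467 (SD, n = 2 each). A comparison of 2 libraries with 2 has 6 possible splits, so a two-sided exact permutation test could not give a p below 0.333, and these library values are given with their spread only.

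**Figure D1:**
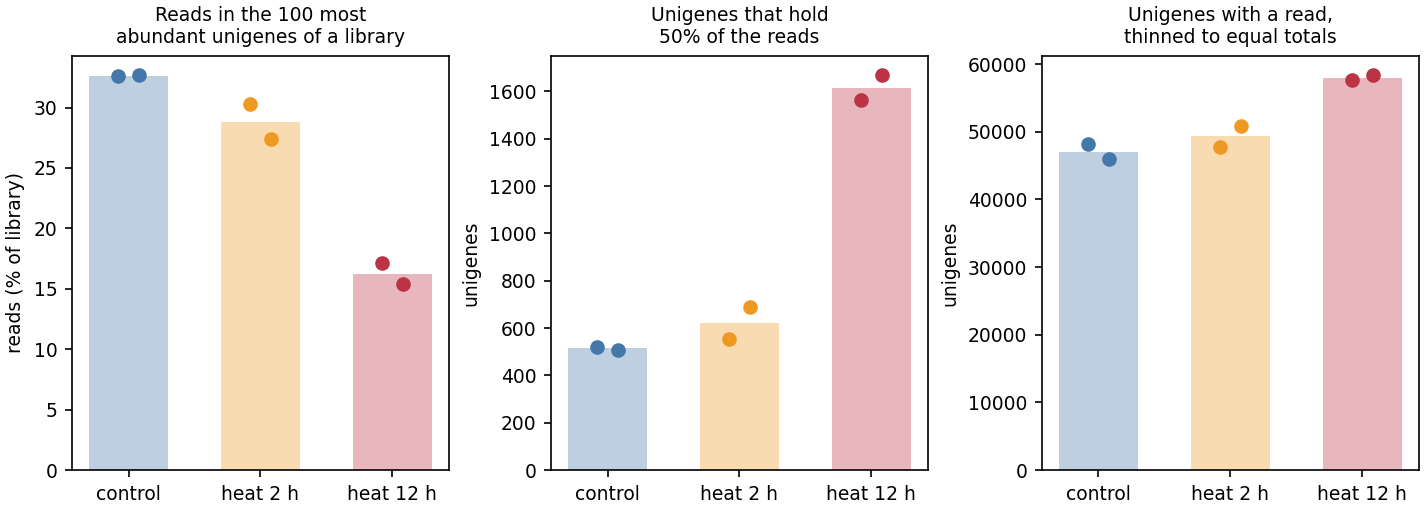
Distribution of reads over unigenes in each of the 6 libraries (points, 2 per group; bars are group means): the percent of reads in the 100 most abundant unigenes of the library, the number of unigenes that hold 50% of the reads, and the number of unigenes with at least 1 read after thinning to equal totals. Both 12 h libraries lie outside the range of the other 4 in every panel, with 1563 and 1667 unigenes holding 50% of the reads against 509 to 689 elsewhere.

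Replicates resembled each other more than libraries of different groups. Log2 CPM over the tested unigenes correlated at r = 0.975 between the controls, 0.972 between the 2 h libraries and 0.977 between the 12 h libraries, against 0.813 to 0.921 between groups; these are correlations across unigenes, which are not independent replicates. The first principal component, with 62.5% of the variance, set the 12 h libraries apart, and the second, with 24.5%, separated the 2 h libraries from the controls. No replicate pair was a duplicate of one library: counts differed by 3.46 to 6.70 times the sampling variance (chi-square per degree of freedom) within groups.

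The first comparison asked which transcripts had changed after 2 h at 42 °C. At this time 3706 unigenes rose and 3719 fell, together 28.7% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The larger changes were mostly rises: 2156 of the risers and 1585 of the fallers changed by at least 2-fold, and 351 against 86 by at least 8-fold. The 351 strong risers took 0.151% ± 0.00849 of the control reads, 2.61% ± 0.234 of the 2 h reads and 4.48% ± 0.527 of the 12 h reads (SD, n = 2). The further rise came from 1 unigene, the most abundant of the 12 h libraries: without it the other 350 took 0.112% ± 0.00626, 2.28% ± 0.201 and 0.843% ± 0.0961. For 74 of them no control read was found, and with unigenes at 0 reads in a group set to the bound that 3 reads over that group allow, 311 rises and 76 falls still reached 8-fold. The 86 strong fallers were minor transcripts, with 0.109% ± 0.007 of the control reads. Both sets were picked by their estimated change at 2 h. For the risers this favours a high share at 2 h against the controls and 12 h.

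By the naming rule, the largest rise after 2 h belonged to unigene c83961_g1. It went from 0.443 ± 0.095 CPM in the controls, 6 reads in all, to 725 ± 87.4 CPM after 2 h (SD, n = 2), a log2 fold change of 10.59 ± 0.73 (SE; edgeR adjusted p = 0.00158), and it stood at 71.3 ± 36.03 CPM after 12 h. Unigene c77567_g1 had no control read and 20.8 ± 9.96 CPM after 2 h, at least 90.2-fold higher (edgeR adjusted p = 4.86e-04), with 3.49 ± 1.06 CPM after 12 h. The largest falls were of c74855_g1, with 15.1 ± 4.08 CPM in the controls, and c36315_g1, with 12.7 ± 2.80 CPM. Neither had a read in any heated library, so they were at least 66.3-fold and 55.3-fold lower after 2 h (edgeR adjusted p = 8.05e-06 and 1.09e-05). Both belong to a set of 16 unigenes with at least 20 reads in each control and none in a heated library, whose reads favoured control replicate 1 by 2.86 to 1 while the library totals stood at 1.44 to 1.

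Without control replicate 1 the number of changed unigenes was 4228 in place of 7425, and 4094 of the 7425 were called again in the same direction. DESeq2 called 4254, and limma on log2(FPKM + 1) called 3967 of the 56390 unigenes it tested.

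The second comparison asked the same after 12 h. Now 7132 unigenes rose and 6291 fell, 52.0% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), with 4758 rises and 3945 falls of at least 2-fold and 923 rises and 747 falls of at least 8-fold. The 747 strongest fallers held 24.5% ± 0.307 of the control reads, 16.8% ± 1.53 of the 2 h reads and 2.56% ± 0.0143 of the 12 h reads (SD, n = 2). The 923 strongest risers went from 0.154% ± 0.00272 of the control reads to 1.19% ± 0.075 after 2 h and 6.98% ± 0.597 after 12 h; without the most abundant unigene of the 12 h libraries the other 922 held 0.114% ± 0.000494, 0.862% ± 0.0419 and 3.35% ± 0.166. No control read was found for 149 of them, and with unigenes at 0 reads set to their bound 832 rises and 743 falls reached 8-fold. Both sets were picked by their estimated change at 12 h, which favours the gap between their control and 12 h shares.

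Most of the unigenes that were abundant before 12 h were lower at 12 h. Ranked by mean CPM over all 6 libraries, 79 of the 100 most abundant unigenes were lower after 12 h, 72 of them by at least 2-fold, and 11 were higher, with a median log2 fold change of -2.61 (quartiles -3.48 and -0.94). After 2 h the same 100 showed 39 lower and 27 higher and a median of -0.23. Of the next 900 by rank, 506 were lower and 174 higher after 12 h, while among the 15828 least abundant 4359 were higher and 2604 lower. The abundance filter keeps a rare unigene that reaches its level in only 2 libraries. At 10 or more reads the 12 h libraries held 25908 and 26913 unigenes, against 20340 to 22801 elsewhere, so part of the excess of rises among the least abundant may come from the filter. Ranking by mean log2 CPM, which gives less weight to a high level in 1 group, left 74 of the top 100 lower and 12 higher, with a median of -2.05. The fall depended on which libraries set the rank. Ranked by the control and 12 h libraries together, 83 of the top 100 were lower and 10 higher, and ranked by the 2 h libraries, which this comparison does not use, 69 were lower and 15 higher, with medians of -2.74 and -2.21. Ranked by the 12 h libraries alone, 39 were lower and 43 higher, with a median of 0.12. Scaled to library totals alone, 73 of the first 100 were lower, but the medians of the lower classes rose: that of ranks 101 to 1000 turned from -0.54 to 0.09, and that of ranks 1001 to 10000 from -0.04 to 0.58. With library totals, the top 100 of the 12 h libraries had 61 higher and 29 lower, with a median of 0.75. Ranked by the 2 h libraries, 25 were then higher and 65 lower. Ranked by the controls these were 4 and 88, and by control and 12 h together 17 and 75.

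**Figure D2:**
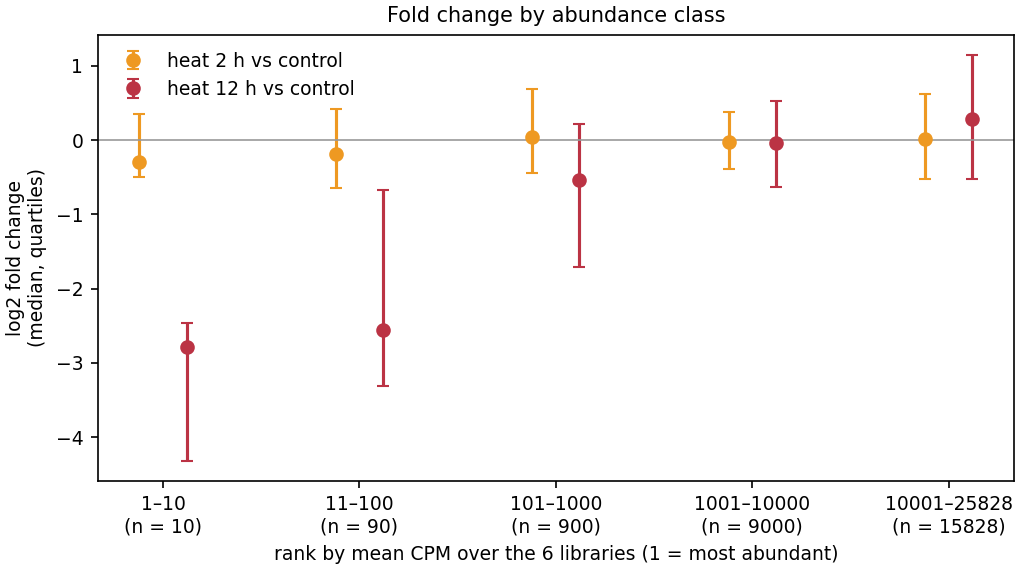
Log2 fold change against control by abundance class (points are medians over unigenes, bars the quartiles; the classes are ranks by mean CPM over the 6 libraries, with the number of unigenes n below each). At 12 h the medians of the classes from rank 1 to 10 and 11 to 100 lie at -2.79 and -2.56, and at 2 h all class medians lie between -0.29 and 0.05. With library totals alone the 12 h median of ranks 101 to 1000 is 0.09.

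The most abundant unigenes of each group, picked by rank after the values were seen, serve as examples only. Picking by level in 1 group favours that group being the higher, and the p-values do not allow for the pick. The top unigene of the controls stood at 25204 ± 1006 CPM, at 20920 ± 1008 CPM after 2 h and at 3259 ± 161 CPM after 12 h (SD, n = 2); its log2 fold change was -0.27 ± 0.12 at 2 h (SE; edgeR adjusted p = 0.114) and -2.95 ± 0.13 at 12 h (edgeR adjusted p = 2.18e-09). The top unigene of the 2 h libraries stood at 24648 ± 1796 CPM in the controls, 21441 ± 4115 CPM after 2 h and 1177 ± 115 CPM after 12 h, where its log2 fold change was -4.39 ± 0.17 (edgeR adjusted p = 8.12e-10). The top unigene of the 12 h libraries rose from 465 ± 33.8 CPM in the controls to 3795 ± 534 CPM after 2 h and 27874 ± 3922 CPM after 12 h, when it alone held 3.63% of the reads. Its log2 fold changes were 3.03 ± 0.15 and 5.91 ± 0.18 (SE; edgeR adjusted p = 7.41e-08 and 1.29e-10).

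By the naming rule, the largest rises after 12 h were of c89759_g1 and c83031_g1. The former had 1 control read and reached 302 ± 38.6 CPM after 12 h, a ratio of 3949 with a 95% counting interval from 709 to 156008 (edgeR adjusted p = 0.00152). The latter also had 1 control read and reached 276 ± 17.5 CPM, a ratio of 3625 with an interval from 650.4 to 143198 (edgeR adjusted p = 4.86e-06). After 2 h they stood at 2.60 ± 2.82 and 2.41 ± 1.69 CPM. The largest falls were of c45128_g1, from 52.5 ± 3.35 CPM to no read after 12 h, and of c78914_g1, from 43.1 ± 0.0772 CPM to no read, at least 398-fold and 330.4-fold lower (edgeR adjusted p = 5.72e-10 and 8.04e-10). Both had already fallen after 2 h, to 11.7 ± 0.429 and 13.5 ± 0.25 CPM.

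The balance of rises and falls at 12 h depended on how libraries were scaled and on the control libraries. Without control replicate 1, under the same scaling, falls slightly outnumbered rises, while the median log2 fold change of all tested unigenes was 0.16. The trimmed-mean scaling used here set factors of 0.860 ± 0.0146 for the controls, 0.879 ± 0.0368 for 2 h and 1.32 ± 0.0299 for 12 h (SD, n = 2), and left the median log2 fold change of all tested unigenes at 0.12. Scaled to library totals alone that median moved to 0.74, and 80.7% of the changed unigenes were higher, 13555 of 16807, in place of 53.1%. The authors' FPKM values are also scaled to totals. Limma on log2(FPKM + 1), which tested 56390 unigenes in place of 25828, gave 80.95% higher among its calls. With DESeq2's size factors in edgeR the balance turned, with 6572 higher and 6803 lower. DESeq2 itself, which also filters and tests in another way, called 8801 unigenes in place of 13423, of which 46.0% were higher.

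The third comparison, of 12 h with 2 h of heat, uses no control library and asks how the response moved on. It shares its 2 h libraries with the first comparison and its 12 h libraries with the second. Between these times 5913 unigenes rose and 5897 fell, 45.7% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), with 3647 rises and 3607 falls of at least 2-fold. By the calls, many unigenes were late responders: 3338 were not called at 2 h but were higher at 12 h than in both other groups, and 2422 were lower than in both. A transient rise was called for 876 unigenes, which were higher after 2 h, lower at 12 h than at 2 h, and not called against control at 12 h. The mirror pattern, a fall at 2 h followed by a rise, held for 624. Between the times 488 and 276 of these differed by at least 2-fold. A unigene not called may still have changed: edgeR recovered 41 of 100 simulated 2-fold changes at 2 h and 40 at 12 h. In that simulation only 100 unigenes changed 2-fold and 100 changed 4-fold, far fewer than were called here. The adjusted threshold was therefore stricter there. With the called unigenes simulated at their fitted changes, of any size, 79.6% and 86.7% were recovered, which overstates the recovery in general. The share missed here is therefore not known. Each pattern joins tests that share a group, and no simulation of unchanged groups was made for these patterns. The counts of these patterns depended on the scaling, the tool and the libraries. With DESeq2 the late responders among the same tested unigenes were 1774 higher and 2012 lower, so that their balance turned, and the transient groups 608 and 289. Without control replicate 1 the late responders were 2841 and 2544 and the transient groups 669 and 392. With library totals alone the late responders were 8098 higher and 1062 lower, the transient groups 467 and 859, and 80.5% of the unigenes changed between the times were higher, against 50.1% here. DESeq2 called 7331 in place of 11810, with 2994 higher and 4337 lower, so falls were the more numerous there.

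Unigenes that rose at both times numbered 2114, of which 543 were higher still at 12 h, 423 had declined from their 2 h level and 1148 did not differ between the times by the test. Of the 2515 lower at both times, 1173 fell further, 134 had partly returned and 1208 did not differ by the test. Against control 429 unigenes were higher at 2 h and lower at 12 h, and 326 were lower at 2 h and higher at 12 h; with library totals alone these were 182 and 790, with DESeq2 236 and 90, and without control replicate 1 they were 187 and 116. Of the 351 strong risers at 2 h, 291 were still called higher at 12 h, 167 were lower at 12 h than at 2 h and 24 were higher. They were picked by a large estimated rise in the 2 h libraries, which favours a lower value at 12 h than at 2 h. The call against control at 12 h uses the same controls, which favours a rise at both times. These counts are therefore descriptive only.

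Both heat comparisons use the same 2 controls, which by itself gives their fold changes a correlation. Across unigenes the fold changes at 2 h and 12 h correlated at r = 0.571 with a covariance of 1.03. In 20 simulations with unchanged heat groups every library, controls included, was drawn from the control means. The mean r was 0.527, the covariance was 0.0697, and at most 3 unigenes were called at both times in either direction. Unigenes without a control read dropped out of these simulations. The observed covariance includes them, among them 149 of the 923 strongest risers at 12 h, so the 2 covariances do not cover the same unigenes. With no unigene changed, few calls remain after adjustment in any case. The share of unigenes with the same sign at both times was 68.1%, between the mean of these simulations, 67.6%, and their highest value, 68.4%. Independent lists of the observed sizes would share 1023 rises and 906 falls, against 2114 and 2515 observed. Such lists treat every unigene as equally likely to be called. At 2 h 342 of the 900 at ranks 101 to 1000 by mean CPM were not called, against 12939 of the 15828 least abundant. At 12 h these were 220 and 8865. Splitting the controls would leave 1 library on each side, so they were not split. Part of the excess may come from the shared controls and from this dependence of calls on abundance. The shared rises and falls were 1140 and 1496 without control replicate 1 and 1166 and 1407 with DESeq2, and the shared falls were 1674 without heat 2 h replicate 2 and 1552 with library totals alone.

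**Figure D3:**
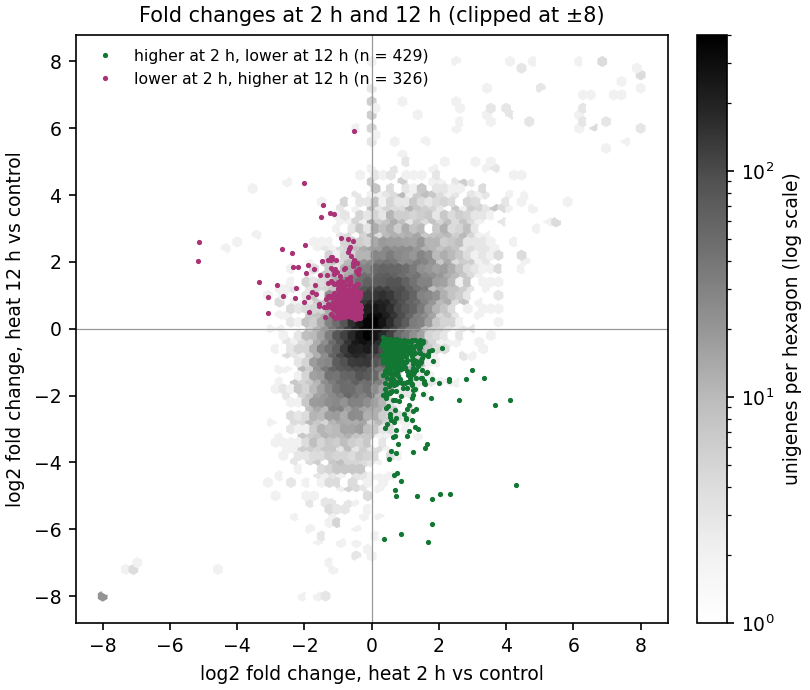
Log2 fold change against control at 2 h (horizontal) and 12 h (vertical) for the 25828 tested unigenes, in hexagons shaded by the number of unigenes on a log scale, with values beyond 8 drawn at 8. Coloured points are unigenes called in opposite directions at the times, 429 higher at 2 h and lower at 12 h and 326 the other way.

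By the naming rule, the largest rises between 2 h and 12 h were of c79168_g2 and c75809_g1. The former had no read at 2 h and 14.9 ± 3.92 CPM at 12 h, at least 64.1-fold higher (edgeR adjusted p = 9.73e-06), with 2 control reads. The latter had 1 read at 2 h and 27.6 ± 11.5 CPM at 12 h, a ratio of 342 with a 95% counting interval from 61.2 to 13539 (edgeR adjusted p = 1.78e-04), and no control read. The largest falls were of c70425_g1, from 13.5 ± 0.357 CPM to no read at 12 h, and of c78914_g1, at least 103.7-fold and 103.1-fold lower (edgeR adjusted p = 9.63e-08 and 1.90e-08). In the controls c70425_g1 stood at 17.0 ± 3.03 CPM, and its change at 2 h did not pass the test (edgeR adjusted p = 0.275).

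**Figure D4:**
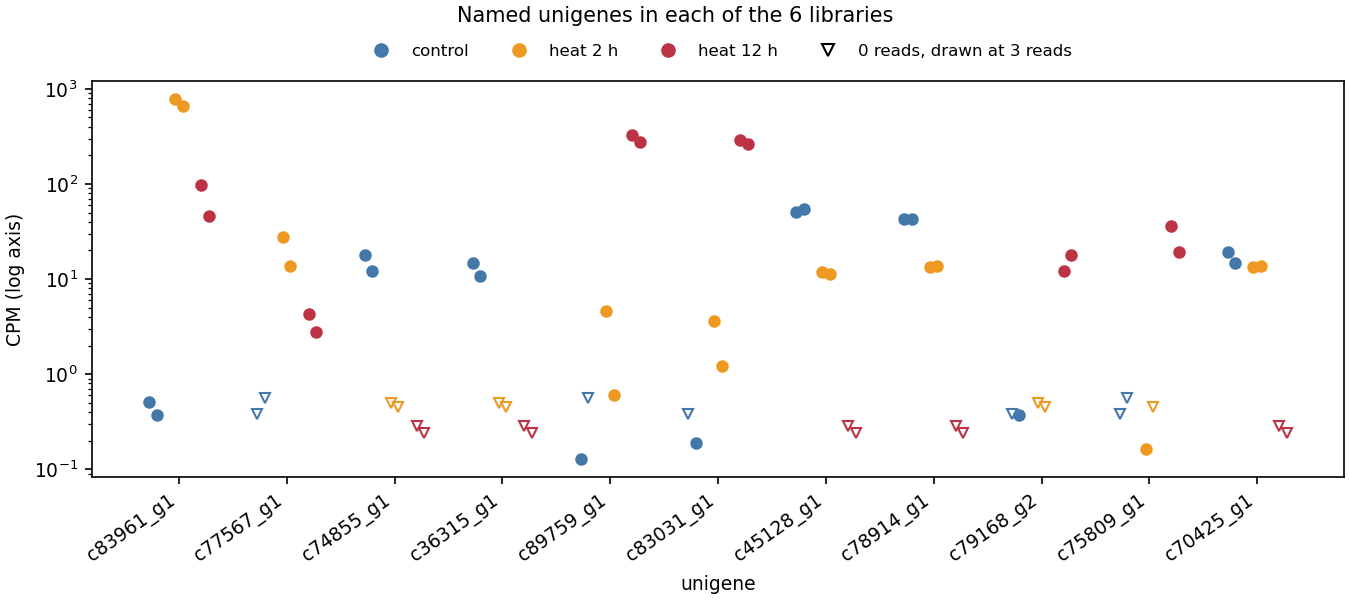
CPM of the 11 named unigenes in each library on a log axis, 2 points per group. Open triangles mark libraries with 0 reads and are drawn at the CPM of 3 reads; c83961_g1 reaches 725 CPM on average at 2 h and 71.3 CPM at 12 h, and c74855_g1 and c36315_g1 have no read in any heated library.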

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

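Each result in this part was picked out because the change against control differed between 2 h and 12 h, as tested by the comparison of 12 h with 2 h (edgeR adjusted p below 0.05). The test was chosen beforehand, and the counts of reversals under other settings and the top unigenes were looked at after the result was seen. Unigenes c79168_g2, c75809_g1, c70425_g1 and c78914_g1 had been named by this same comparison, so their passing it here adds no evidence. The other named unigenes here, and the top unigenes at 2 h and 12 h, were picked on libraries this comparison also uses. That pick favours their passing as well.

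Reversals against control numbered 429 for unigenes higher at 2 h and lower at 12 h, and 326 for unigenes lower at 2 h and higher at 12 h. Between 12 h and 2 h, 385 and 289 of them differed by at least 2-fold. The numbers were 182 and 790 with library totals alone, 236 and 90 with DESeq2, and 187 and 116 without control replicate 1, so both their size and their balance depend on these choices.

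Among the named unigenes, the log2 fold change at 12 h lay below that at 2 h by -3.35 for c83961_g1 (edgeR adjusted p = 0.00562) and by -2.58 for c77567_g1 (edgeR adjusted p = 0.00224). It lay above by 6.89 for c89759_g1 (edgeR adjusted p = 0.00242) and by 6.86 for c83031_g1 (edgeR adjusted p = 9.81e-06). With 1 read at 2 h, c75809_g1 had a ratio of 12 h to 2 h of 342, with a 95% counting interval from 61.2 to 13539 (edgeR adjusted p = 1.78e-04). With no read at 12 h, c45128_g1 was at least 89.2-fold lower than at 2 h, c78914_g1 at least 103.1-fold and c70425_g1 at least 103.7-fold. With no read at 2 h, c79168_g2 was at least 64.1-fold higher at 12 h.

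The top unigene of the controls moved by -2.68 on the log2 scale between 2 h and 12 h, the top unigene of the 2 h libraries by -4.19, and the top unigene of the 12 h libraries by 2.88.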

How the results depend on the processing

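Library totals, counts per component, removal of the 100 most abundant unigenes and the other rankings were added after seeing the data. DESeq2 called 4254, 8801 and 7331 unigenes in the comparisons of 2 h with control, 12 h with control and 12 h with 2 h, against 7425, 13423 and 11810, and 1166 rises and 1407 falls shared by both times against 2114 and 2515. Limma tested 56390 unigenes with its filter and 88871 without it, against 25828 in the main test, so these counts come from sets of unlike size. At 2 h it called 3967 on log2(FPKM + 1) and 4685 on log2(FPKM + 0.1). Without a filter it called 2484, of which 1734 changed by at least 2-fold, against 3741 in the main test. At 12 h it called 13446 and 13472 by at least 2-fold with the filter and pseudocounts of 1 and 0.1, against 8703. Library totals alone left 1552 shared falls. Leaving out 1 library at a time gave 4228 to 7878 calls at 2 h, 10015 to 13815 at 12 h and 9198 to 11393 between 12 h and 2 h; by at least 2-fold the counts were 2545 to 3895, 7275 to 9140 and 6246 to 7269. Shared rises ranged from 1140 to 2082 and shared falls from 1496 to 2496; without control replicate 1 they were 1140 and 1496, and without heat 2 h replicate 2 the shared falls were 1674. In these fits the lone library is assumed to vary like the other groups. The median of the 100 most abundant unigenes at 12 h was -2.61, -1.99 with library totals and -2.05 when ranked by mean log2 CPM; ranked by the control and 12 h, the 2 h, the control or the 12 h libraries it was -2.74, -2.21, -3.03 and 0.12, so the last ranking turned its sign. The remaining 130 values of these counts under the alternatives stayed within 1.5 times the main count, and each named unigene kept its direction and call wherever it was tested. Under library totals 139 of the 13423 calls at 12 h were called in the opposite direction; limma gave 47, 60 and 16 opposite calls with log2(FPKM + 1), log2(FPKM + 0.1) and no filter, and the other edgeR settings on unigenes and DESeq2 gave none. The cause of these differences was not tested. The replicate number as a block gave 8682, 14499 and 12927 calls. Deviations of same-numbered libraries correlated at 0.00784 between control and heat 2 h and at 0.0353 between control and heat 12 h. Between heat 2 h and heat 12 h they correlated at 0.285. The third principal component, with 5.6% of the variance, separated replicate 1 (-41.8 at 2 h, -23.0 at 12 h) from replicate 2 (41.4 and 20.9). A factor tied to the replicate number in the heated libraries is therefore not excluded, and the main test did not model it. Gene list tests, with camera at a preset or an estimated correlation, with fry or with the replicate number as a block, were not run because the files do not pair IDs with names. Depth limits statements on unigenes near 3 reads.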

Other observations

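Directions within components, unigenes read in 1 condition and replicate ratios were looked at after the data were seen. The tests of depth, abundant unigenes, scaling, time of day and foreign RNA in this part were chosen after the result was seen; the test of unigene length was planned before its result was seen.

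Unigenes that the assembly placed in one component, which can be related gene copies or variants, mostly moved together. Of the components with at least 2 called unigenes at 12 h, 241 (19.5%) held both a rise and a fall, against a median of 654 (619 to 699) when directions were shuffled 100 times. At 2 h the numbers were 74 of 519 against 270 (247 to 305), and between 12 h and 2 h 170 of 1079 against 579 (532 to 622). Reads shared between such unigenes would also make them move together. Several unigenes were read in both libraries of 1 condition and nowhere else: at 10 or more reads per library there were 28 for the controls, 0 for 2 h and 35 for 12 h, and 22 were read in all 4 heated libraries and in no control. At 20 or more reads, 6 unigenes were found in control replicate 2 alone (613 reads), 6 in heat 2 h replicate 2 alone (200 reads) and 1 in heat 12 h replicate 2 alone (61 reads).

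The 8th most abundant unigene differed between replicates in every group, by ratios of 2.24, 1.40 and 1.84 for control, 2 h and 12 h, where the median ratio over the 100 most abundant was at most 1.17 in any group; its change at 12 h did not pass the test (edgeR adjusted p = 0.143). The unigene at rank 89 had ratios of 2.39, 1.43 and 2.05, and its log2 fold change of -2.72 ± 0.70 (SE) at 12 h passed the test (edgeR adjusted p = 0.0486). For both, replicate 1 was the higher in the controls and at 12 h, and replicate 2 at 2 h.

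More unigenes were detected at 12 h than in the controls. The values argue against the library totals as the cause. After thinning to equal totals the ratio of 12 h to control was 1.23. The lowest 12 h library exceeded the highest other library by 6730 unigenes, more than the largest gap between replicates, 3154. Without the 100 most abundant unigenes the ratio was 1.17 and the gap 4541 against 2656, so the reads freed by these 100 may account for part of the excess but not for all of it. Falls at 12 h reached beyond these 100, with 506 of the next 900 by rank lower. Scaled to library totals, the median log2 fold change of the tested unigenes at 12 h was 0.74. Equal totals thus still left most of them more reads at 12 h, and reads freed by further fallers were not tested as a cause. A broader change of the leaf transcriptome with 12 h of heat stays open as a hypothesis, as does RNA of other origin, which was not tested.

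The 100 most abundant unigenes by mean CPM over all libraries were lower at 12 h, which did not hold for the 100 most abundant at 12 h (median 0.12). With library totals the median of the latter was 0.75. For the former the choice of scaling is argued against as the whole cause, since their highest median over 4 scalings was -1.99. Unigene length is argued against too, since fold change and length were almost uncorrelated over the tested unigenes (Spearman rho -0.00139). There was thus little trend on length to remove, and the median after removing it was -2.74 (quartiles -3.59 and -1.10). Time of day cannot be told apart from heat, because 0 untreated libraries were taken after 0 h, and leaf transcripts that follow the day may fall over 12 h without heat. An effect of prolonged heat on transcripts abundant before 12 h is the hypothesis the design names, and it stays untested against that.

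The 16 unigenes read at 20 or more reads in both controls and never under heat include the named fallers c74855_g1 and c36315_g1. If all came from one foreign source, such as a microbe on the control plants, with the same RNA make-up in both controls, their read ratio between the controls would be equal. It ran from 1.12 to 4.61, with a chi-square per degree of freedom of 6.36. Among 1000 sets of other unigenes matched on control reads the median was 1.65, the 95th percentile 3.72 and the 99th percentile 6.87, so the ratios vary more than in most sets but short of the level set for excluding such a source. A source whose own expression differed between the controls would give unequal ratios, so the test could not exclude one source in general. One foreign source, several sources, a difference between plants and a loss of expression under heat cannot be told apart by this value.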
